A study of Homo sapiens with 6 samples.

How the data were processed

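RNA was sequenced from 3 independent, untreated cultures of the H23 cell line and 3 of the A549 cell line. Per the labels' protocols, total RNA was taken with a phenol-based reagent from cultures near confluence, and all 6 libraries came from a stranded total RNA kit with ribosomal RNA removal. H23 was grown in RPMI 1640 and A549 in DMEM, both with fetal bovine serum, per the labels' protocols. Groups and replicate numbers were taken from the labels.

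Each library came with a table of genes and a table of transcripts, in the column layout of RSEM. STAR 2.6.0c, RSEM 1.3.0 and the genome build hg19 are named in the submitters' processing notes, without options, annotation release or strand setting. The deposited expected counts are RSEM's estimated read counts per gene or transcript, not scaled to depth, per the file headers. The deposited TPM values, RSEM's transcript abundances scaled for length and depth, summed to a fixed total in each library. The deposited FPKM values were not used here beyond their column sums. The deposited percent values give each transcript's share of its gene's transcripts. The deposited lengths, in bases, served to sort transcripts by size. Genes carry symbols and transcripts carry RefSeq identifiers, as the files give them, for 27968 genes and 70006 transcripts. The tables hold no coordinates and the reference at hand follows GRCh38, so no positions are given, and that reference served for names, gene order and GC content.

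Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 15426 genes. TMM factors of 0.985 to 1.02 scaled the libraries. Levels are TMM-normalised CPM, computed from the deposited expected counts, as mean ± SD over the 3 libraries of a line. The lines were compared with edgeR's robust quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. Log2 folds are A549 over H23. Their standard errors were taken as the absolute log2 fold over the square root of F and are approximate. The common biological coefficient of variation was 0.168. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so calls rest on the model fitted across genes.

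The depth sets a floor. Where a line had 0 counts over its 3 libraries, the fold was taken against 3 counts over the group and is given as a lower bound. Where it had 1 to 3 counts, the ratio is given with a 95% counting interval. Floors and intervals cover counting error only. Reads shared by close paralogs or repeated gene copies were divided by RSEM's model, and that division carries an error the tests leave out.

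The comparisons, tests, gene lists, most alternatives and the rule for naming genes were set before the data were examined. The rule named 6 genes per direction with the largest log2 fold among genes past the test, without overlap of the lines and with a mean TPM of at least 20 in the higher line, and 5 per direction with the largest difference of mean TPM. RNA genes under 200 bases were left out of these groups. It also allowed up to 3 members per direction from a list and members of the driver and identity list. It further allowed the 5 genes with the largest change of leading transcript among those past the usage test. That change was ranked by the smaller change of the pair of leading transcripts, in percentage points. Any other gene was chosen after its values had been seen.

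Of 26 fixed gene lists, 23 had at least 5 tested members and were tested with limma's camera (limma 3.58.1), with the correlation between genes preset at 0.01, then estimated, and with fry. Fry asks whether a list moves one way on balance and does not compare it with other genes. The blood cell and endothelial lists were too short for these tests, and the mitochondrially encoded mRNAs were not analysed here. Transcript usage was tested with edgeR's diffSpliceDGE gene-level F test on 24779 transcripts of 7539 genes. A leading transcript was the one with the highest share in all 3 libraries of a line, in genes with TPM of at least 5 in all libraries, with a change of at least 20 percentage points.

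Each test was run on simulated counts drawn from the means of these genes. In a simulation of the A549 against H23 gene test over 15164 genes, 16% of genes changed by 0.5 on the log2 scale were found, 76% at 1, 94% at 2 and all at 4, with 18 false calls among 14964 unchanged genes, 11.2% of the calls. In a simulated camera test over 15169 genes, 8 of 200 random lists had a p under 0.05 and a list of 30 genes shifted by 1 was found. Random lists are not chosen for genes that move together, so that rate need not hold for the fixed lists. Their estimated correlations ran from -0.151 for the cancer-testis list to 0.828 for the ribosomal protein list. In a simulated usage test over 3130 genes with a pair of transcripts, 11 of 2951 unchanged genes were called, 31.4% of the calls.

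Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), other low-count filters, unrounded counts, omission of some fixed-list RNAs, a block for the replicate number, other thresholds and the omission of each library. Others were chosen after seeing the data: coding genes without histone genes, removal of a trend with GC content and length, TPM rescaled without short RNAs and histone genes, and coding transcripts alone. GC content came from matched GENCODE transcript sequences for 15165 tested genes, 98.3%, and the trend was fitted with splines of 5 degrees of freedom on genes above 10 CPM. The short RNAs left out in the rescaling were non-coding and under 300 bases. Further steps used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.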

Results

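RNA sequencing was compared between 2 established human lung cancer cell lines, A549 and H23. Both lines are kept as models of lung adenocarcinoma. Each line was grown as 3 independent cultures without treatment, H23 in RPMI 1640 and A549 in DMEM, so medium and line changed together. The RNA make-up of the libraries also changed with the line, as described below, so folds cannot be credited to the line alone. RNA was collected near confluence. The question set by the study's title was how the transcriptomes of the 2 lines differ. The H23 libraries held 37295989, 29395795 and 42421642 estimated read counts in replicates 1, 2 and 3, and the A549 libraries held 24441832, 25348083 and 23399562. At these depths a floor of 3 counts in a single library was worth 0.0707 to 0.102 CPM, counts scaled to library size, in H23 and 0.118 to 0.128 CPM in A549. Levels below are TMM-normalised CPM, given as mean ± SD over the 3 libraries of a line. Log2 folds are A549 over H23, given with an approximate standard error and an adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rank correlations of gene levels across genes were 0.969 to 0.975 between libraries of the same line and 0.881 to 0.889 between lines. No pair of libraries was close enough to be a repeat of the same library, with a chi-square per gene of at least 3.81.

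A549 and H23 differed in most of the genes that could be tested, and the sharpest contrasts were genes present in only 1 of the lines. HAVCR1, a cell surface receptor known from injured kidney epithelium, stood at 211 ± 3.47 CPM in A549 and at 0 counts in H23, at least 7750-fold higher (edgeR adjusted p = 6.06e-07). The hair keratin gene KRT81 rose from 0.10 ± 0.0870 CPM in H23 to 3116 ± 40.7 CPM in A549, and its log2 fold of 15 ± 0.29 became 15.81 without H23 replicate 2. The aldo-keto reductase AKR1C2 went from 0.101 ± 0.0428 to 2861 ± 54.4 CPM, a log2 fold of 14.75 ± 0.19. In the other direction, the secreted WNT ligand WNT2 stood at 64.6 ± 8.28 CPM in H23 against 0 counts in A549, at least 1560-fold higher in H23. The metallothionein gene MT1E, at 84.0 ± 20.4 CPM in H23, was also at 0 counts in A549, at least 2020-fold higher in H23. KRT81, AKR1C2 and MT1E have close paralogs, so reads assigned to them could belong in part to a relative.

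Among abundant transcripts, the ferritin light chain FTL was at 5672 ± 486 CPM in A549 and 1605 ± 75 CPM in H23, a log2 fold of 1.82 ± 0.09. The glycolytic enzyme GAPDH, often used as a reference gene, was higher in H23, at 17268 ± 3583 against 5986 ± 113 CPM (log2 -1.53 ± 0.16, edgeR adjusted p = 0.000111). The ribosomal protein genes RPS18 and RPS27 were higher in H23, with log2 folds of -1.47 ± 0.11 and -1.84 ± 0.10. The actin-binding peptide gene TMSB10 was also higher in H23, with a log2 fold of -0.58 ± 0.10.

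Over the whole table, 11910 of 15426 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 77.2% of those tested. Of these, 5801 were higher in A549 and 6109 higher in H23, and 7733 differed at least 2-fold, 3786 of them higher in A549. No A549 library carried a count for 214 of the genes called higher in H23, and no H23 library for 158 of those called higher in A549. The values of the 3 libraries of each line did not overlap for 12659 genes, 82.1% of those tested, where chance gives 10%. That held for each gene described here as higher in a line. The median log2 fold over all tested genes was -0.03. It moved to -0.16 with upper quartile factors and to -0.41 on log2(TPM + 1), where 3869 genes were called higher in A549 and 8356 higher in H23. Leaving out H23 replicate 1, which stood apart from the other H23 libraries, gave 13774 genes.

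Targets of NRF2, the transcription factor that drives genes against oxidative stress, were higher in A549. Of 37 tested members, 35 were higher in A549 and 1 higher in H23, and 36 passed when adjusted over the list alone. AKR1B10, an aldo-keto reductase, rose from 0.225 ± 0.0659 CPM in H23 to 4129 ± 146 CPM in A549 (n = 3 each, log2 14.18 ± 0.17, edgeR adjusted p = 5.28e-08). Its neighbour AKR1B15 was at 25.1 ± 2.31 CPM in A549 and at 0 counts in H23, at least 921-fold higher, and the high identity of the pair leaves the split of reads uncertain. SLC7A11, the cystine transporter, and NQO1, a quinone reductase, were named after their values had been seen and had log2 folds of 5.43 ± 0.34 and 1.09 ± 0.11. The exception was the ferritin heavy chain FTH1, at 2397 ± 198 CPM in H23 and 1033 ± 53.8 CPM in A549 (log2 -1.21 ± 0.09), opposite to FTL. EPHX1 had a log2 fold of -0.12 ± 0.15 and did not pass. The list median was 3.33 and camera gave an adjusted p of 3.9e-16, with adjusted p = 0.0943 with an estimated correlation, in a range of 3.26e-33 to 0.0943 over its camera alternatives. The drug and aldehyde metabolism list, which shares no gene with the NRF2 list, went both ways, with 14 of 31 members higher in A549, 13 higher in H23 and 27 passing when adjusted over the list alone. Its camera adjusted p was 0.451. In that list ALDH1A1, a retinaldehyde dehydrogenase, went from 0.559 ± 0.214 to 8174 ± 65.2 CPM (log2 13.87 ± 0.25) and the glutathione transferase MGST1 had a log2 fold of 6.34 ± 0.14. UGT8, an enzyme of galactolipid synthesis, was higher in H23, with a log2 fold of -6.34 ± 0.38.

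Single genes that are often altered in lung cancer, and single genes of chromatin remodelling, differed between the lines. SMARCA2, a SWI-SNF ATPase, was at 1.94 ± 0.324 CPM in H23 and 50.4 ± 0.449 CPM in A549 (log2 4.70 ± 0.14, edgeR adjusted p = 5.93e-07). Its paralog SMARCA4 was higher in H23, at 28.9 ± 2.18 against 11.4 ± 0.466 CPM (log2 -1.34 ± 0.10). The cell cycle inhibitor genes CDKN2A and CDKN2B were at 19.8 ± 2.25 and 1.96 ± 0.459 CPM in H23 and at 0 counts in A549, at least 477-fold and 47.3-fold higher in H23. Their neighbour MTAP, an enzyme of methionine salvage, was detected in both lines, at 24.1 ± 5.10 CPM in H23 and 7.61 ± 0.604 CPM in A549 (log2 -1.66 ± 0.17). The receptor tyrosine kinases AXL, EGFR and MET were higher in A549, with log2 folds of 2.41 ± 0.09, 2.06 ± 0.17 and 1.67 ± 0.08. MYCN, at 1.66 ± 0.809 CPM in H23, was at 0 counts in A549, at least 40.1-fold higher in H23. KEAP1 and STK11 were higher in A549, with log2 folds of 0.94 ± 0.14 and 0.80 ± 0.12, and neither passed on log2(TPM + 1), with limma adjusted p of 0.0669 and 0.14, the highest of their alternatives, against lowest values of 2.59e-13 and 9.12e-12.

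Of 27 tested driver and identity genes, 11 were higher in A549, 10 higher in H23 and 6 did not pass, and 21 passed when adjusted over the list alone. The list median was 0.16, fell to -0.36 on log2(TPM + 1), and camera gave an adjusted p of 0.851. NFE2L2, which encodes NRF2, did not pass, with a log2 fold of -0.23 ± 0.23. Without H23 replicate 1, NFE2L2 stood at 0.11 with an edgeR adjusted p of 0.0498, in a range of 0.0116 to 0.729 over its alternatives. MYC and CUL3 did not pass, with log2 folds of 0.17 ± 0.08 and 0.44 ± 0.25, and each passed in both directions among its alternatives. MYC stood at 0.23 without H23 replicate 1 (edgeR adjusted p = 4.29e-05) and at -0.37 on log2(TPM + 1) (limma adjusted p = 0.00229), with a highest adjusted p of 0.67. CUL3 stood at 0.79 without H23 replicate 1 (edgeR adjusted p = 3.55e-14) and at -0.88 with a trend with GC content and length removed (5.66e-06), with a highest adjusted p of 0.744. For ERBB2, with a log2 fold of 0.50 ± 0.19 and an edgeR adjusted p of 0.0464, the omission of A549 replicates 1, 2 and 3 gave 0.104, 0.0776 and 0.0896, in a range of 4.92e-06 to 1 over its alternatives. RB1 was higher in A549, with a log2 fold of 0.82 ± 0.18 that turned to -0.34 once that trend was removed (edgeR adjusted p = 0.00688, in a range of 5.38e-15 to 0.114 over its alternatives). BRAF, with a log2 fold of -0.38 ± 0.15 and an edgeR adjusted p of 0.0575, passed without H23 replicates 1, 2 and 3 (0.011, 0.0404 and 0.0483), in a range of 2.72e-06 to 0.229 over its alternatives. In the SWI-SNF list, 5 of 24 members were higher in A549 and 13 higher in H23, with 19 passing when adjusted over the list alone and a camera adjusted p of 0.223. ARID1A went from 196 ± 32.0 CPM in H23 to 17.8 ± 1.61 CPM in A549, a log2 fold of -3.46 ± 0.16, and SMARCD3 had a log2 fold of -2.14 ± 0.11.

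**Figure D1:**
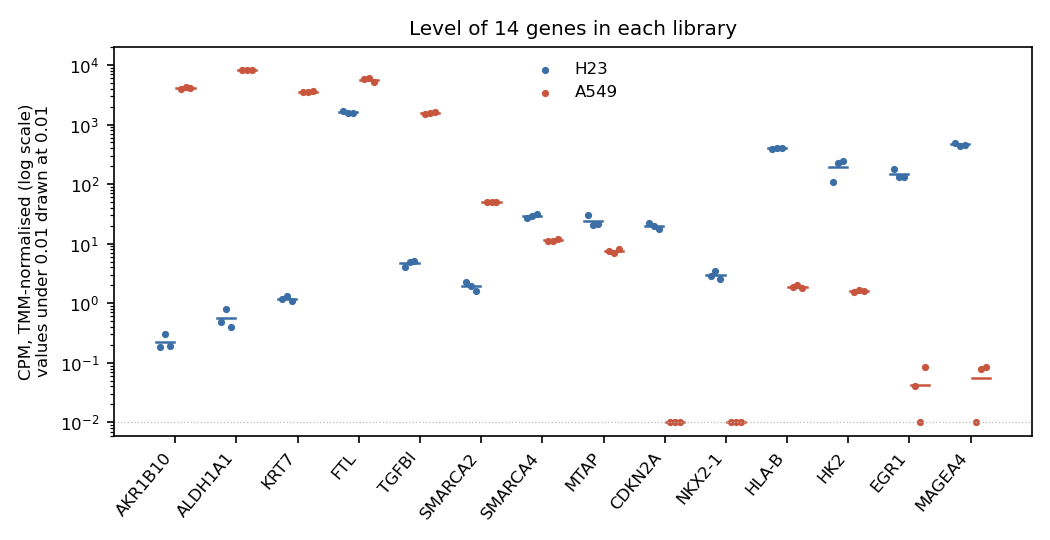
Level of 14 genes in each of the 6 libraries, in TMM-normalised CPM on a log scale, with a bar at the mean of each line (n = 3) and values under 0.01 CPM drawn at 0.01. The 3 A549 points of AKR1B10 lie near 4129 CPM against 0.225 CPM in H23, and those of CDKN2A and NKX2-1 are at 0 counts.

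Epithelial and mesenchymal markers did not divide between the lines. The simple-epithelium keratin KRT7 rose from 1.18 ± 0.112 CPM in H23 to 3562 ± 48.4 CPM in A549 (log2 11.56 ± 0.12, edgeR adjusted p = 4.04e-08), and the epithelial transcription factor ELF3 had a log2 fold of 11.06 ± 0.17. The splicing regulator ESRP2 and the mucin MUC1, both epithelial, were higher in H23, with log2 folds of -6.84 ± 0.21 and -5.91 ± 0.25. Of 28 tested epithelial genes, 15 were higher in A549, 9 higher in H23 and 24 passed when adjusted over the list alone. Their median log2 fold was 0.40, or -0.11 on log2(TPM + 1), with a camera adjusted p of 0.223. TGFBI, a matrix protein induced by TGF-beta, was at 1535 ± 59.7 CPM in A549 and 4.72 ± 0.544 CPM in H23 (log2 8.35 ± 0.13), and THY1 was at 12.9 ± 1.07 CPM against 0 counts, at least 474-fold higher in A549. The mesenchymal cadherin CDH11, at 70.3 ± 11.9 CPM in H23, was 2540 (95% counting interval 703 to 21000) times its A549 level, and the mesenchymal transcription factor PRRX1 was 894 (95% counting interval 161 to 35300) times its A549 level. Of 31 mesenchymal genes, 16 were higher in A549, 11 higher in H23 and 27 passed when adjusted over the list alone, with a median of 0.78 and a camera adjusted p of 0.208. The list passed without H23 replicate 1 (camera adjusted p = 0.0269), and its adjusted p ran from 0.0269 to 0.468 over its camera alternatives.

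Lineage genes of the lung and of neuroendocrine cells were likewise mixed. NKX2-1, the lineage factor of the distal lung, was at 2.95 ± 0.440 CPM in H23 and at 0 counts in A549, at least 71.1-fold higher in H23 (edgeR adjusted p = 6.73e-05). FOXJ1, the master factor of motile cilia, was also higher in H23, at 33.3 ± 1.38 against 0.443 ± 0.0295 CPM. FOXA2, a foregut endoderm factor, was higher in A549 with a log2 fold of 6.03 ± 0.14, and the gastric-type mucin MUC5AC was at 2.44 ± 0.213 CPM in A549 against 0 counts in H23, at least 89.6-fold higher. Of 13 tested lung lineage genes, 7 were higher in A549 and 4 higher in H23, 11 passed when adjusted over the list alone, and the camera adjusted p was 0.461. NRCAM, a neuronal adhesion molecule, was at 209 ± 7.47 CPM in A549 and 0.0399 ± 0.0352 CPM in H23, a log2 fold of 12.33 ± 0.31 that became 11.68 without H23 replicate 3. The neurofilament gene NEFL and the secretory granule gene SCG2 were higher in H23, with log2 folds of -4.41 ± 0.12 and -4.64 ± 0.16. All 19 tested neuroendocrine and neuronal genes passed, also when adjusted over the list alone, with 8 higher in A549 and 11 higher in H23. Their median was -1.97 and the camera adjusted p was 0.316.

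Among the positional HOX genes and the cancer-testis genes, single genes also differed, as did 77.2% of all tested genes. HOXC10 was at 43.1 ± 3.01 CPM in H23 and 0.454 ± 0.0953 CPM in A549 (log2 -6.55 ± 0.17, edgeR adjusted p = 2.99e-07) and HOXD9 had a log2 fold of -4.77 ± 0.27, while HOXA10 and HOXA7 were higher in A549 with log2 folds of 2.53 ± 0.34 and 3.80 ± 0.58. Of 35 HOX genes, 9 were higher in A549 and 18 higher in H23, 27 passed when adjusted over the list alone, and the camera adjusted p was 0.202. The antigen gene MAGEA4, normally restricted to germ cells, was at 465 ± 28.5 CPM in H23 and 0.0554 ± 0.0481 CPM in A549 (log2 -12.93 ± 0.28). MAGEA12 was at 0 counts in H23 and 1.63 ± 0.245 CPM in A549, at least 59.9-fold higher, with the reservation that MAGEA genes are near-identical. All 7 tested cancer-testis genes passed, also when adjusted over the list alone, with 4 higher in A549 and 3 higher in H23. Their median of 0.45 differed in sign from their mean of -0.76 and from the direction of the camera test (adjusted p = 0.576).

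Genes of antigen presentation were lower in A549. HLA-B, a classical class I heavy chain, was at 396 ± 10.4 CPM in H23 and 1.88 ± 0.115 CPM in A549 (n = 3 each, log2 -7.72 ± 0.10, edgeR adjusted p = 5.99e-08). The class II gene HLA-DRB1, at 3.72 ± 0.322 CPM in H23, was 269 (95% counting interval 48.2 to 10600) times its A549 level. HLA genes are highly variable, and how fully the reads of each line's own alleles aligned to the reference was not measured, which leaves their levels uncertain. The class I transactivator NLRC5 went the other way, from 0.375 ± 0.136 CPM in H23 to 6.16 ± 0.331 CPM in A549 (log2 4.01 ± 0.24). Of 20 tested members, 3 were higher in A549, 16 higher in H23 and 19 passed when adjusted over the list alone. The median was -1.30 and the camera adjusted p was 0.00156, with adjusted p = 0.13 with an estimated correlation, in a range of 1.37e-05 to 0.13 over its camera alternatives. Interferon-stimulated genes were split, 13 of 23 higher in A549 and 8 higher in H23, with 21 passing when adjusted over the list alone and a camera adjusted p of 0.317. IFITM3 and ISG15 were higher in H23, with log2 folds of -5.48 ± 0.15 and -3.31 ± 0.19. SAMD9 was higher in A549, with a log2 fold of 7.49 ± 0.37 that became 8.51 without H23 replicate 1.

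Secreted inflammatory factors went both ways. CXCL5, a neutrophil attractant at 71.1 ± 3.31 CPM in A549, was 2610 (95% counting interval 895 to 12700) times its H23 level, and the cytokine IL11 rose from 2.11 ± 0.483 to 57.6 ± 1.16 CPM (log2 4.76 ± 0.18, edgeR adjusted p = 1.19e-06). CCL20 was at 362 ± 68.0 CPM in H23 and 0.225 ± 0.143 CPM in A549, a log2 fold of -10.65 ± 0.32 that became -11.25 without A549 replicate 3. CCL5, at 21.8 ± 7.74 CPM in H23, was 1580 (95% counting interval 283 to 62300) times its A549 level. Of 17 tested cytokines and chemokines, 6 were higher in A549 and 8 higher in H23, 14 passed when adjusted over the list alone, and the camera adjusted p was 0.851.

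Targets of the YAP-TEAD complex were more often higher in A549, with a camera result near the threshold. The growth factor gene TGFB2 and the nuclear factor gene ANKRD1, both targets of YAP, went from 3.49 ± 1.11 and 0.184 ± 0.0993 CPM in H23 to 143 ± 2.01 and 7.48 ± 0.964 CPM in A549 (log2 5.35 ± 0.23 and 5.33 ± 0.32, edgeR adjusted p = 2.1e-06 and 8.84e-06). CYR61 and CTGF, other classical YAP targets, were higher in H23, with log2 folds of -2.17 ± 0.10 and -0.64 ± 0.19. CTGF was named after its values had been seen. Of 22 YAP-TEAD targets, 13 were higher in A549, 5 higher in H23 and 18 passed when adjusted over the list alone. The median was 0.92 and the camera adjusted p was 0.0469, with adjusted p = 0.184 with an estimated correlation. The list did not pass without H23 replicate 2 (camera adjusted p = 0.071) or without H23 replicate 3 (0.0664), and its adjusted p ran from 0.014 to 0.184 over its camera alternatives.

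RAS-MAPK output genes were more often higher in H23. The immediate early gene EGR1, at 148 ± 29.4 CPM in H23, was 3570 (95% counting interval 1220 to 17300) times its A549 level, and FOS went from 34.9 ± 1.57 to 1.06 ± 0.108 CPM (log2 -5.03 ± 0.13, edgeR adjusted p = 2.74e-07). The EGFR ligand EREG and the phosphatase DUSP4 were higher in A549, with log2 folds of 4.09 ± 0.14 and 2.87 ± 0.30. Of 22 members, 5 were higher in A549, 13 higher in H23 and 18 passed when adjusted over the list alone, with a median of -1.22. The camera adjusted p of 0.0536 did not pass, and it was 0.0269 without H23 replicate 1, in a range of 0.0169 to 0.21 over its camera alternatives.

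Cholesterol synthesis genes were higher in A549. The sterol enzyme MSMO1 rose from 9.50 ± 1.42 to 62.5 ± 1.12 CPM (log2 2.72 ± 0.13, edgeR adjusted p = 3.14e-06) and the sterol sensor partner INSIG1 had a log2 fold of 2.23 ± 0.14. PMVK and FDPS, earlier enzymes of the pathway, were higher in H23, with log2 folds of -1.69 ± 0.10 and -0.96 ± 0.07. Of 25 members, 18 were higher in A549, 4 higher in H23 and 22 passed when adjusted over the list alone. The median was 0.75 and the camera adjusted p was 0.00949, with adjusted p = 0.13 with an estimated correlation, in a range of 0.00244 to 0.13 over its camera alternatives.

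Glycolysis genes were more often higher in H23. Hexokinase HK2 was at 192 ± 74.2 CPM in H23 and 1.59 ± 0.0501 CPM in A549 (log2 -6.91 ± 0.39, edgeR adjusted p = 6.56e-06) and the glucose transporter SLC2A3 was at 599 ± 189 against 8.45 ± 1.41 CPM (log2 -6.15 ± 0.31). Another glucose transporter, SLC2A1, and the pyruvate kinase gene PKM were higher in A549, with log2 folds of 1.0 ± 0.30 and 0.83 ± 0.22, and neither passed on log2(TPM + 1), with limma adjusted p of 0.182 and 0.267, the highest of their alternatives, against lowest values of 2.66e-13 and 1.06e-12. Of 23 members, 4 were higher in A549, 15 higher in H23 and 19 passed when adjusted over the list alone. The median was -0.93 and the camera adjusted p was 0.0469, with adjusted p = 0.679 with an estimated correlation. The camera call did not pass without H23 replicate 2 (0.071), without H23 replicate 3 (0.0664) or with a trend for GC content and length removed (0.263), in a range of 3.22e-06 to 0.679 over its camera alternatives. In H23 replicate 1 the list's median lay at -0.71 on the log2 scale against H23 replicates 2 and 3, or at -0.45 after that trend was removed.

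Proliferation genes and ribosomal protein genes differed in both directions. TYMS, which makes thymidylate for DNA synthesis, was at 607 ± 25.5 CPM in H23 and 45.2 ± 2.05 CPM in A549 (log2 -3.75 ± 0.09, edgeR adjusted p = 2.13e-07), and the mitotic transcription factor FOXM1 had a log2 fold of -2.26 ± 0.15. CENPF and TOP2A, genes of the G2 and M phases, were higher in A549, with log2 folds of 2.57 ± 0.60 and 1.98 ± 0.42 that became 3.65 and 2.67 without H23 replicate 1. CCNE2 was higher in A549 with a log2 fold of 1.07 ± 0.12, which turned to -0.27 with the GC content and length trend removed. Of 30 proliferation genes, 6 were higher in A549, 16 higher in H23 and 21 passed when adjusted over the list alone, against 22 over all genes. Their median was -0.41 and the camera adjusted p was 0.0723, or 0.0396 without H23 replicate 1, in a range of 0.0366 to 0.208 over its camera alternatives. RPL37 was higher in H23, with a log2 fold of -1.82 ± 0.13, and RPS6 was higher in A549, with a log2 fold of 1.19 ± 0.12. Of 40 ribosomal protein genes, 10 were higher in A549, 19 higher in H23 and 29 passed when adjusted over the list alone. Their median of -0.16 became 0.05 with the GC content and length trend removed, and the camera adjusted p was 0.316.

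**Figure D2:**
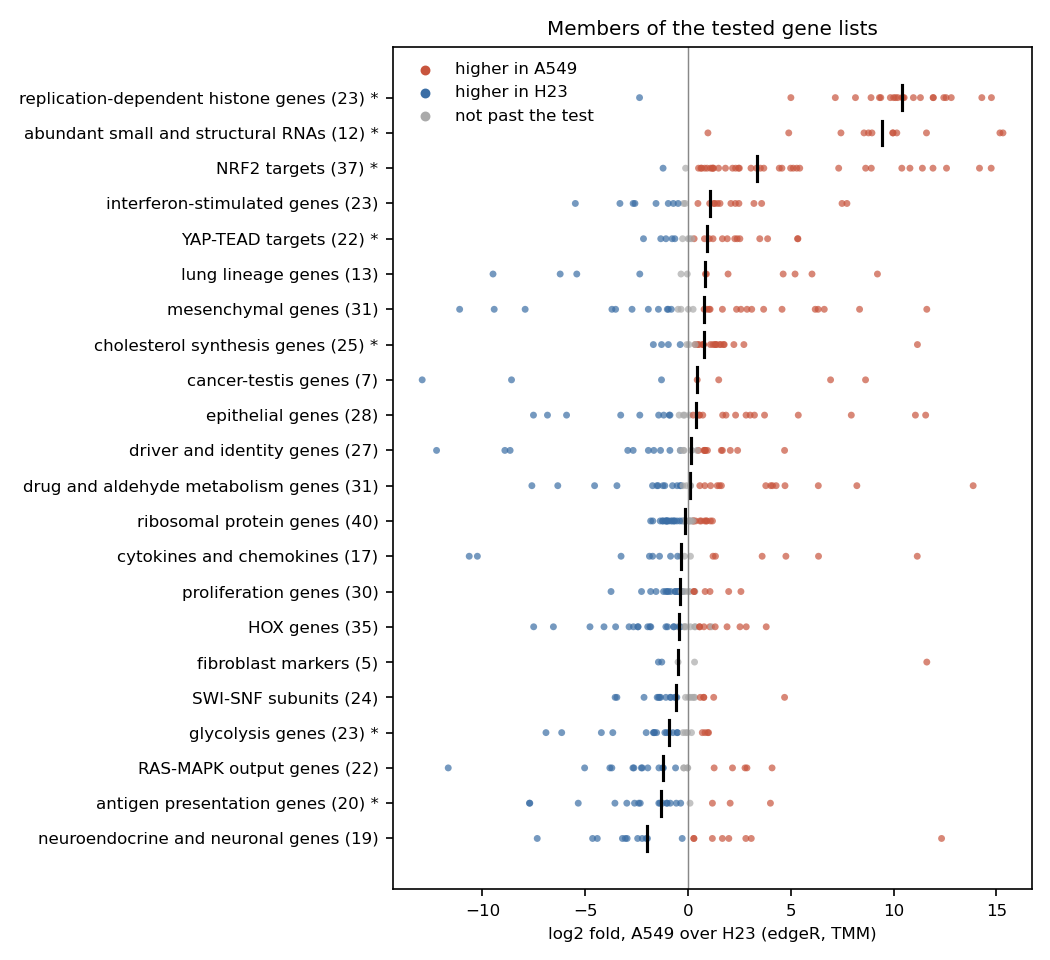
Log2 fold (A549 over H23) of each tested member of 22 gene lists, with the number of members in brackets, a black tick at the list's median and an asterisk where camera's adjusted p with the preset correlation was under 0.05. Points are coloured by the gene's edgeR call, and fitted folds of genes at 0 counts in 1 line depend on the prior count. The NRF2 targets have 35 of 37 members higher in A549, and no list kept its call with an estimated correlation.

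The widest group difference lay in RNAs that carry no poly(A) tail. Of 23 replication-dependent histone genes fixed as a list, 22 were higher in A549, 1 higher in H23, and all 23 passed when adjusted over the list alone. HIST1H3C was at 114 ± 3.77 CPM in A549 and 0 counts in H23, at least 4190-fold higher. HIST1H2BH was the exception, with a log2 fold of -2.36 ± 0.31. It was barely detected, at 0.728 ± 0.107 CPM in H23 and 0.139 ± 0.0291 CPM in A549, from 80 and 10 counts. The list's median was 10.41 and its camera adjusted p was 5.38e-20, with adjusted p = 0.13 with an estimated correlation, in a range of 2.06e-59 to 0.13 over its camera alternatives. Of the small and structural RNAs, all 12 tested were higher in A549, also when adjusted over the list alone, with a median of 9.45 and a camera adjusted p of 3.5e-09, or adjusted p = 0.0943 with an estimated correlation, in a range of 7.83e-18 to 0.0943 over its camera alternatives. RPPH1, the RNA of ribonuclease P, was at 0.262 ± 0.278 CPM in H23 and 10942 ± 522 CPM in A549, and RMRP, its relative in ribonuclease MRP, at 0.264 ± 0.231 and 10169 ± 772 CPM. Their log2 folds of 15.32 ± 0.52 and 15.17 ± 0.42 became 16.72 and 16.12 without H23 replicate 1. The telomerase RNA TERC, at 69.0 ± 4.24 CPM in A549, was 3800 (95% counting interval 1050 to 31400) times its H23 level. The mitochondrial ribosomal RNA RNR2 was higher in H23, at 12907 ± 5096 against 110.2 ± 21.6 CPM (log2 -6.87 ± 0.36). The 18S ribosomal RNA copies RNA18SN2 to RNA18SN5, which share all their reads, were each at 50.8 ± 19.2 CPM in H23 and 0 counts in A549, at least 1220-fold higher in H23. The 45S and 28S ribosomal RNA copies, looked at after their values had been seen, went the other way, with all 10 higher in A549. Copies of a kind repeat the same values, so RNA45SN1 and RNA28SN1 stand for all of them, with log2 folds of 6.99 ± 0.18 and 2.30 ± 0.33.

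The same contrast appeared in the make-up of each library. Non-coding RNAs shorter than 300 bases, 2521 genes in the tables, held 1.36% ± 0.0644 of counts in A549 and 0.00171% ± 0.000578 in H23 (SD, n = 3). Because TPM divides by length, their share of TPM was 32.0% ± 2.05 in A549 and 0.178% ± 0.0734 in H23. The 74 named histone genes that carry a replication-dependent name summed to 42063 ± 1028 TPM in A549 and 462 ± 95.6 TPM in H23. The labels name the same total RNA kit with ribosomal RNA removal for all 6 libraries. TPM sums to a fixed total in each library, so a larger share for these genes leaves less for the others, and directions here rest on TMM-scaled counts.

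**Figure D3:**
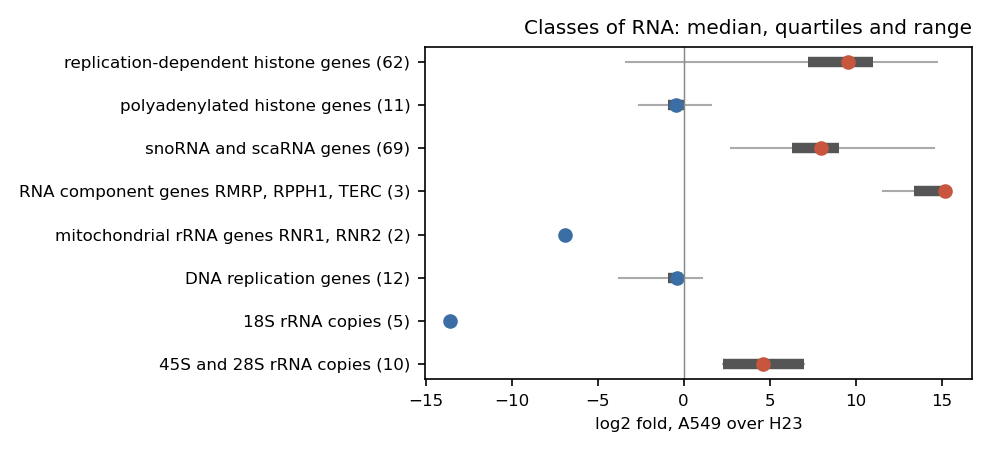
Log2 fold (A549 over H23) by class of RNA, with the number of tested genes in brackets, a dot at the median, a thick bar from the lower to the upper quartile and a thin line over the range. Replication-dependent histone genes have a median of 9.57 and polyadenylated histone genes a median of -0.42. The classes were drawn up after the data had been seen, the 45S and 28S copies hold only 2 distinct values, at the ends of their bar, and folds of genes at 0 counts depend on the prior count.

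Few markers of other cell types could be tested. Of the blood cell list, 3 of 18 members could be tested and CD8A was the member past the test, at 6.97 ± 0.557 CPM in H23 and 0.292 ± 0.0876 CPM in A549 (log2 -4.57 ± 0.22, edgeR adjusted p = 3.67e-06). Of the endothelial list, 2 of 13 could be tested, with ESAM higher in A549 (log2 1.59 ± 0.20) and ERG at 7.17 ± 0.332 CPM in H23 against 0 counts in A549, at least 173-fold higher in H23. Both passed when adjusted over the list alone, as did the blood cell member, and these 2 lists were too short for camera. Of 14 fibroblast markers, 5 could be tested. THY1 was higher in A549, LUM and COL1A1 were higher in H23 with log2 folds of -1.28 ± 0.29 and -1.44 ± 0.16, and 3 passed when adjusted over the list alone. The fibroblast median of -0.49 differed in sign from the mean of 1.75 and from the direction of the camera test (adjusted p = 0.91).

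The deposited transcript tables allowed a comparison of which transcript of a gene was used. HIST1H2BK used the transcript NM_080593, of 839 bases, for 98.6% ± 0.476 of its output in H23 and 5.16% ± 0.286 in A549, where the 498-base NM_001312653 took 94.8% ± 0.286 (SD, n = 3, edgeR usage test, adjusted p = 3.87e-08). HIST1H2BD moved in the same way, from the 813-base NM_138720 at 72.8% ± 11.9 in H23 to the 487-base NM_021063 at 98.5% ± 0.0493 in A549. Both genes carry a replication-dependent name, a class far lower in the H23 libraries. A different RNA selection could also give these changes, which was not tested. MKI67, the proliferation marker Ki-67, used NM_001145966 for 93.1% ± 1.78 in H23 and 26.7% ± 2.91 in A549, where the longer NM_002417 took 73.3% ± 2.91 (edgeR usage test, adjusted p = 0.000128). BIRC3, an inhibitor of apoptosis, used NM_182962 for 74.8% ± 0.0987 in H23 and NM_001165 for all of its output in A549, while the gene's total level did not pass the gene test (edgeR adjusted p = 0.419). PCGF5, a Polycomb subunit, went from the non-coding NR_046435 at 77.5% ± 0.318 in H23 to NM_001257101 at 71.4% ± 6.58 in A549 (edgeR usage test, adjusted p = 0.0452).

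In total, 1944 of 7539 genes with at least 2 tested transcripts passed the usage test, 25.8%, and 2739 had an unadjusted p under 0.05. The count was 955 with the Simes combination of the transcript tests and 1249 with a block for the replicate number. The transcript in the lead differed between the lines in 217 of 5012 genes with TPM of at least 5 in all libraries. Of these, 167 passed the usage test and 50 did not pass the gene test. For some of them, among them TUBB, MICA and HSPA1B, the leading entries of the lines were copies under the same RefSeq identifier. Such a gene is not shown to change its transcript form, and the usage test also took these copies as separate transcripts. Shares are model estimates whose assignment error the test leaves out. Library make-up changed with the line, so a call is not shown to reflect transcript choice by the cells. On simulated data the usage test found 23.9% of genes in which 1 transcript changed by 2 on the log2 scale and 2.30% of those changed by 1, so a gene outside the 1944 is not shown to have equal usage. Of its calls on those data 31.4% were false, a share that depends on how many genes change.

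**Figure D4:**
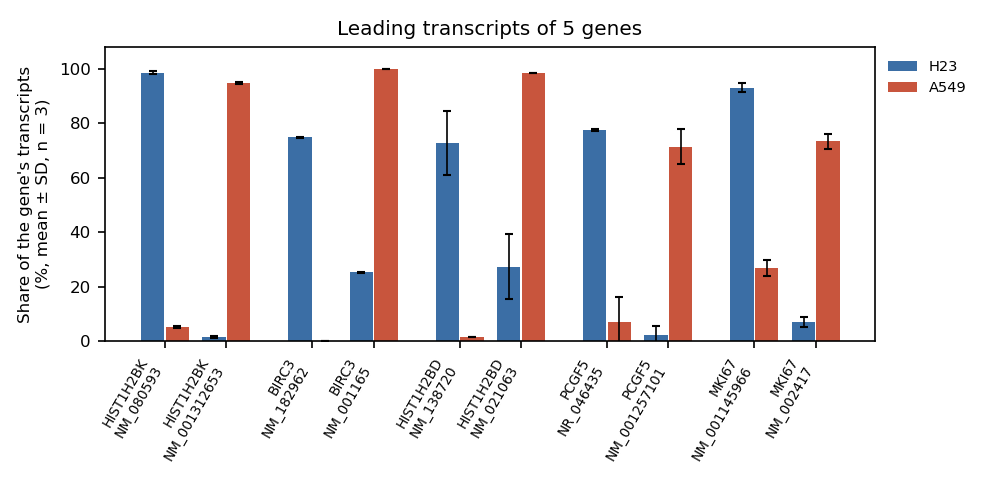
Share of a gene's transcripts, in percent, taken by the transcript that leads in H23 and the transcript that leads in A549. Bars show the mean and error bars the SD (n = 3). The 5 genes had the largest change among those past the usage test, ranked by the smaller change of the pair of transcripts. In each of the 5 genes the leading transcript of H23 falls below 27% in A549.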

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

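The tests on protein-coding genes without histone genes, on counts with the GC content and length trend removed and on rescaled TPM were chosen only after the result was seen. Genes past the test numbered 10459 to 13774 over the changes of tool, scaling, filter, genes entering and library, or 10262 at an adjusted p under 0.01, against 11910. Genes past the test with a change of at least 2-fold numbered 7733, or 6114 when tested against a 2-fold change. Both counts stayed within 1.5 times their value under every alternative run, but the genes behind them changed. Of the 11910 genes, 10300 kept their call and direction with the trend removed and 9957 on log2(TPM + 1). In the other direction, 279 genes were called with the trend removed, 121 on log2(TPM + 1) and 3 on rescaled TPM. Leaving out each library in turn gave 11037 to 13774 genes, 5372 to 6839 of them higher in A549 and 5665 to 6935 higher in H23, with the highest total without H23 replicate 1.

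For 161 named genes, 2968 values from the alternatives kept their direction and call, 15 gained a call, 19 lost it and 7 changed direction, and the cause was not tested. For 22 of the 23 tested lists, 374 values kept direction and call, 24 gained a call, 25 lost it and 11 changed direction. Directions changed on log2(TPM + 1) for CUL3 (-0.0769) and MYC (-0.37), and on rescaled TPM for NF1 (0.0614). They changed with the GC content and length trend removed for CCNE2 (-0.27), CUL3 (-0.88) and RB1 (-0.34). Of these, MYC on log2(TPM + 1) and CUL3 and RB1 with the trend removed passed in the new direction. Leaving out each library in turn put NFE2L2 between -0.39 and 0.11, with a change of sign without H23 replicate 1.

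The number of lists past the camera test, 8, changed under several alternatives. It was 5 with limma-voom, 5 with the filter of 50 counts, 4 on rescaled TPM, 0 with an estimated correlation and 21 with fry, which asks another question. It was 3 without the small RNA and histone genes of the fixed lists and 3 with coding genes alone, which remove 2 of the lists by construction. Leaving out each library gave 5 to 11 lists, with 5 without H23 replicate 2 and without H23 replicate 3, and 11 without H23 replicate 1. For the other changes the cause was not tested.

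The glycolysis and YAP-TEAD lists no longer passed in several fits, against medians of -0.93 and 0.92 as reported, and the cause was not tested. The medians in that order were -0.87 and 0.93 with limma-voom, -1.39 and 0.33 on log2(TPM + 1), -0.92 and 0.92 with the filter of 50 counts, -0.92 and 0.92 without the fixed small RNA and histone genes, -0.91 and 0.93 with coding genes alone, and -0.76 and 0.88 on rescaled TPM. With upper quartile factors the YAP-TEAD list no longer passed, at 0.79, and with the trend removed the glycolysis list no longer passed, at -0.93. Leaving out each library gave -1.17 to -0.74 for glycolysis and 0.81 to 0.9999 for YAP-TEAD targets, with neither past the test without H23 replicate 2 or without H23 replicate 3. With an estimated correlation none of the 8 lists passed, and the medians included 3.33 for NRF2, -1.30 for antigen presentation, 0.75 for cholesterol synthesis, -0.93 for glycolysis, 0.92 for YAP-TEAD, 10.41 for histones and 9.45 for small RNAs.

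Some lists passed that had not, and the cause was not tested. RAS-MAPK genes passed without a filter (-1.20), with the replicate block (-1.20) and with the trend removed (-1.37), and lay between -1.31 and -1.08 over the omitted libraries. Proliferation genes passed on log2(TPM + 1) (-0.93) and without a filter (-0.39), and lay between -0.44 and -0.35 over the omitted libraries. Mesenchymal genes passed with the trend removed (0.82) and lay between 0.65 and 0.94 over the omitted libraries. All 3 of these lists passed without H23 replicate 1. Epithelial genes passed with the trend removed (0.33), and ribosomal protein genes on log2(TPM + 1) (-0.69). With fry, lists that had not passed did so at medians of 0.16 (driver), 0.40 (epithelial), 0.78 (mesenchymal), 0.85 (lung), -1.97 (neuroendocrine), 1.05 (interferon), -0.41 (proliferation), -1.22 (RAS-MAPK), 0.12 (drug metabolism), -0.42 (HOX), 0.45 (cancer-testis), -0.58 (SWI-SNF) and -0.49 (fibroblast).

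Lists whose test changed direction, at times with the sign of the median kept, had members going both ways and did not pass in those fits. The cause was not tested. The cytokine list did so on log2(TPM + 1) (-0.72), without a filter (0.13), with the trend removed (-0.49) and with fry (-0.36). The cancer-testis list did so with limma-voom (0.45) and on log2(TPM + 1) (-0.14), the driver list with the trend removed (-0.38), and the fibroblast list with limma-voom (-0.46) and on rescaled TPM (-0.16). The fibroblast median lay between -0.77 and -0.37 over the omitted libraries, and the test's direction turned without H23 replicate 1 and without A549 replicate 3.

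Genes with different transcript usage numbered 1944, with 955 by the Simes combination and 1249 with the replicate block, and 1430 to 2307 over the omitted libraries, and the cause was not tested. The pairing of replicate numbers had no basis in the data: deviations of libraries with the same number correlated across genes at 0.103, -0.129 and 0.188, and those with different numbers at -0.21 to 0.197. The blocked fit gave 11691 genes. Genes with another leading transcript numbered 217, with 84 at a TPM of at least 20, 332 at a TPM of at least 1 and 86 at a change of at least 40 points, which follow from the number of genes that meet each limit, and 229 to 280 over the omitted libraries. Depth limits the genes at 0 in one line, whose folds are lower bounds.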

Other observations

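The family comparison, the neighbour search and all tests on the classes of RNA, on H23 replicate 1 and on the splits of the libraries were chosen only after the result was seen. Among 172 gene families sharing a symbol stem with at least 10 tested members, 3 passed camera with the preset correlation. Of 13 keratin genes, 10 were higher in A549 and 1 higher in H23, with a median log2 fold of 3.61 (camera adjusted p = 0.00267). Of 11 aldo-keto reductase genes, 8 were higher in A549 and 3 higher in H23, with a median of 6.25 (camera adjusted p = 0.00522). This family shares genes with the NRF2 list, among them AKR1B10, AKR1B15 and AKR1C2, so it is not a separate result. Some members are close paralogs, whose reads were divided by RSEM's model. Of 14 annexin genes, 11 were higher in A549 and 2 higher in H23, with a median of 1.44 (adjusted p = 0.0442). The medians were 3.84, 6.78 and 1.84 with the GC content and length trend removed. None passed with an estimated correlation, where the adjusted p was 0.967 for all 3.

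At 3 places, stretches of 3 neighbouring genes were on in 1 line and off in the other. The fibrinogen genes FGB, FGA and FGG were above 1 CPM in A549 and below 0.1 CPM in H23, with FGA at 29.8 ± 3.02 CPM in A549 and 0 counts in H23, at least 1090-fold higher. UGT1A9, UGT1A7 and UGT1A6, which share exons, were also on in A549 alone. KLRK1, KLRC4 and KLRC3, receptor genes known from natural killer cells, were on in H23 alone, with KLRC3 at 19.3 ± 3.44 CPM in H23. The CDKN2A output of H23 came to 98.8% from NM_058195, the transcript that encodes p14ARF, and NM_000077, which encodes p16, was at 0. Median log2 folds rose with transcript length, from -0.36 for the shortest of 6 bins to 0.42 for the longest, and ran from -0.26 to -0.08 once the trend with GC content and length was removed.

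RNAs without poly(A) tails differed between the lines, with a median log2 fold of 9.57 over 62 tested replication-dependent histone genes, 57 of them higher in A549, and of 8.01 over 69 snoRNA and scaRNA genes, all higher in A549. A larger share of A549 cells in S phase is unlikely to be the cause, since the upper quartile of the log2 folds of 12 DNA replication genes was -0.0932. A different RNA selection of the H23 and A549 libraries could give this pattern, for 2 reasons. The median of replication-dependent histone genes exceeded that of 11 polyadenylated histone genes by 9.99. Mitochondrial ribosomal RNA went the other way, with a median of -6.89. The other ribosomal RNAs were split, with the 18S copies, all 5 of them, higher in H23 and all 10 of the 45S and 28S copies higher in A549. Whether RNA selection could give that split was not tested. HIST1H2BK and HIST1H2BD used their shorter transcripts in A549 and their longer ones in H23. The selection of RNA, for which the labels name a single kit, and a difference between the lines in the RNAs themselves, which was not tested, both stay open, since every library of a line carried the pattern.

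H23 replicate 1 stood apart from H23 replicates 2 and 3. The SD across genes of its log2 difference from them was 0.541, against 0.13 between replicates 2 and 3. GC content and length accounted for 54.7% of the variance of that difference over 9298 genes, against 8.37% between replicates 2 and 3 and 4.42% for A549 replicate 1 against the other A549 libraries. A recovery that depended on GC content and length is a candidate explanation for most of this deviation, and no biological explanation was tested for it.

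Hypoxia-induced genes were lower in H23 replicate 1. Of 32 genes written down as a list after the lowest genes had been seen, 28 were measured, with a median log2 difference of -0.77. It stayed at -0.76 after the GC content and length trend was removed, though some of the 28 were among the 60 lowest genes. The other 19 had a median of -0.56 after the trend was removed, where 95% of 10000 random lists lay between -0.175 and 0.101, which argues against that trend as the whole cause. Another state of that culture, in oxygen, glucose or density, could give this median of -0.56, and the labels give none of these for a single culture.

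The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, and for each of 4 counts 1 split, the real one, reached the real value. The real split gave 11910 genes and 7733 genes at 2-fold, and the highest other split 0 of each. It gave 8 lists against 6, and 1944 genes with different transcript usage against 20. Every other split put libraries of both lines in each group, so the difference between the lines widened the spread within groups. Low counts in those splits therefore cannot tell whether the real counts exceed chance.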
